A study of Mus musculus with 24 samples.

How the data were processed

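Primary microglia from the cortex of mice aged 1 to 3 days after birth were profiled by QuantSeq 3′ mRNA sequencing in the forward version (Lexogen), from RNA taken with a Quick-RNA MicroPrep kit (Zymo Research). Per the labels, the mice were homozygous for APOE3 or APOE4 and carried human TREM2 as CV/CV or R47H/CV, and cells received vehicle or 0N4R tau fibrils, with 3 libraries in each of 8 groups. Sex was labelled as not determined. The authors deposited a table of read counts per gene for the 24 libraries, and per the submitters' processing notes the genome build was GRCm38 (mm10) and DESeq2 1.38.3 was used. The aligner and the counting rule are not given in the sources used here. Raw reads were not analysed here. Nothing in the labels says that the replicates of a group are separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

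The table held 54532 genes by symbol, of which 28375 had at least 1 count. A symbol matched 1 gene of GENCODE M21 in 98.4% of cases, and positions are from that annotation. Symbols that occurred more than once (102 symbols, 207 entries) held 0.134% of counts and were kept apart, and 27 entries with names turned into dates held 0.126%. No column was left unmapped. Library totals ran from 16607753 to 27367610 counts. After the TMM scaling described below, 1 count equalled 0.0296 to 0.0741 CPM. The protocol as labelled names no unique molecular identifiers, and errors derived from counts cover counting error only where amplification copies were not removed. Between replicates of a group log2 CPM correlated at 0.983 to 0.993.

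Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. All 24 libraries were fitted in a single edgeR quasi-likelihood model with a mean for each of 8 groups, after TMM scaling and filterByExpr with a count minimum of 10, which left 14443 genes. From it came 20 comparisons: tau against vehicle in each of 4 genotypes and averaged over them, R47H/CV against CV/CV in 4 settings, APOE4 against APOE3 in 4 settings, 6 differences between such effects by pairs of factors and 1 difference by all 3. P-values were adjusted by Benjamini and Hochberg within each comparison, and genes under 0.05 were called. Group levels are means of TMM-scaled CPM. Standard errors of log2 fold changes came from the same model. Where a group held no counts, levels are given and no fold.

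Gene lists were written from general knowledge before the data were examined, 27 in all: interferon-stimulated genes, cGAS-STING pathway, NF-kB targets and inflammatory cytokines, senescence and secretory phenotype, disease-associated microglia genes, homeostatic microglia genes, lysosome and phagocytosis, cholesterol biosynthesis, LXR targets, NRF2 targets, glycolysis and hypoxia, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, proliferation, antigen presentation, unfolded protein and integrated stress response, TGF-beta and matrix response, p53 targets, immediate early genes, ribosomal proteins, sex-linked genes, and markers of astrocytes, oligodendrocyte lineage, neurons, fibroblasts and mural cells, endothelium, and border macrophages and monocytes. Each list with at least 5 tested members was compared with all other tested genes by camera, with a preset correlation between genes of 0.01 and again with the correlation estimated, and tested on its own by fry. The p-values were adjusted over the lists of a comparison. Medians and counts of members called over all genes are given, and for the main lists the counts called when adjusted over the list alone.

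Genes were named by a rule set before the data were examined. For each comparison it took the 6 largest changes in each direction among called genes with a mean of at least 10 CPM in the higher group, a symbol that is not a predicted one and no overlap of libraries between groups. It added up to 4 members with the smallest adjusted p of each list where the list passed or at least 3 members were called. It always took Apoe, Trem2, Mb21d1, Tmem173, Cdkn1a, Cdkn2a, Isg15, Ifit3, Cxcl10, Il1b, Tnf, P2ry12 and Cst7. The text leaves some of the first and second kinds out for length. Correlations between effects are described without a p-value because genes are not independent.

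Alternatives fixed before the data were examined were RLE scaling, DESeq2 with its Wald test, no filter, the replicate number as a block, a fit of only the 6 libraries compared, the omission of each library in turn, the estimated correlation, and fry. Removal of genes on the X and Y chromosomes from the comparisons of genotypes was added after seeing the data, once the sex-linked genes were seen to differ. For each comparison libraries were also regrouped with the group sizes kept, in all 10 splits for 3 against 3 and in a random sample of 100 splits, the real one included, for larger designs. The pipeline was tested on simulated counts with 50 changed genes at each of 4 folds (1.25, 1.5, 2 and 4). For tau in APOE3 CV/CV edgeR recovered 14, 25, 32 and 47 of them with 5 wrong calls, and for R47H in APOE3 vehicle 15, 33, 41 and 46 with 10 wrong calls. For a difference between effects, R47H by APOE4 in vehicle, it recovered 5, 24, 34 and 43 with 12 wrong calls. A changed list was found by camera and by fry in the 5 comparisons simulated. Of 26 unchanged lists camera called 0 in each, and fry called 1 for APOE4 in CV/CV vehicle and 0 in the other 4. The simulated genes varied independently and few were changed. The simulation therefore tests neither lists of correlated genes nor scaling where most genes change, as with tau.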

Results

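Microglia grown from the cortex of newborn mice were compared in 8 groups of 3 libraries, 24 in all. The mice were homozygous for human APOE3 or APOE4 and carried human TREM2 as the common variant on both alleles (CV/CV) or as R47H on one of them (R47H/CV). Each of these 4 genotypes received vehicle or tau fibrils of the 0N4R form. Library totals ran from 16607753 counts (APOE3 CV/CV with tau, replicate 3) to 27367610 (APOE4 CV/CV with vehicle, replicate 3), and 14443 genes were tested. Levels are in CPM with the standard deviation of 3 libraries, and log2 fold changes carry their standard error. FDR stands for p-values adjusted over all genes tested or over all lists.

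Mitochondrial transcripts made up 1.94% of counts in APOE3 R47H/CV with vehicle and 1.37% with tau, against 1.11% and 0.810% in APOE3 CV/CV. They were lower in APOE4, at 0.959% and 0.496% in CV/CV and 0.670% and 0.430% in R47H/CV. The scaling factors separated the treatments, with group means of 1.15 to 1.23 in vehicle and 0.797 to 0.875 in tau. TMM scaling takes most genes as unchanged, whereas 66.57 to 70.83% of genes were called with tau in each genotype. Small changes with tau, and the balance of rises and falls, therefore depend on the scaling. The 20 most abundant genes of a library took 14.8 to 20.9% of its counts by group mean. The biological coefficient of variation was 7.59%. Tau samples of APOE3 R47H/CV varied most, as at Il1b (1674 ± 1260 CPM) and Tnf (282.6 ± 144 CPM).

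The counts at the mouse Trem2 and Apoe genes, whose human forms the mice carry, were examined before any other gene. Trem2, a lipid receptor of microglia (chromosome 17, 48346401 to 48354147 on the plus strand of GRCm38), stood at 234 ± 2.84 CPM in APOE3 CV/CV and 244.5 ± 3.34 in APOE4 CV/CV under vehicle. In R47H/CV it stood at 100.4 ± 12.1 and 96.2 ± 14.5 (n = 3). Under tau it was at 9.50 ± 0.780 CPM in APOE3 CV/CV and 5.72 ± 0.395 in APOE4 R47H/CV. Apoe, a lipid carrier (chromosome 7, 19696109 to 19699188 on the minus strand), ranged from 28.8 ± 1.93 CPM in APOE4 CV/CV to 56.2 ± 4.10 in APOE3 R47H/CV under vehicle. How transcripts of the human forms were assigned to these mouse genes is not given in the sources used here. The 3′ protocol is meant to read transcript ends, and where the reads fall along these genes was not examined, so neither level tests the genotype.

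Sex was not determined, and the sex-linked genes differed between genotypes. Xist, the transcript that silences one X chromosome (X, 103460366 to 103483254), was at 163 ± 9.50 CPM in APOE3 CV/CV, 0 in APOE3 R47H/CV, 321 ± 21.9 in APOE4 CV/CV and 597 ± 69.0 in APOE4 R47H/CV under vehicle. With tau it was at 139 ± 7.96, 0.0363, 264 ± 15.7 and 579.5 ± 33.2. Ddx3y, on the Y chromosome (1260771 to 1286629), was at 53.2 ± 4.62, 68.3 ± 2.77, 41.1 ± 1.02 and 0 under vehicle, and Eif2s3y, Kdm5d and Uty were also 0 in both APOE4 R47H/CV groups. APOE3 R47H/CV samples therefore carried next to no Xist and APOE4 R47H/CV samples carried no Y-linked counts. Every comparison of genotypes below is at the same time a comparison of samples that differ at these genes. Where R47H or APOE4 is said to raise or lower genes, this describes a difference between such groups and not its cause. If the libraries of a genotype came from a single pool of cells, the FDR values below do not cover variation between animals.

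Tau fibrils changed most of the genes tested in APOE3 CV/CV microglia. Nos2, which makes nitric oxide, stood at 3722 ± 342 CPM with tau and 1.03 ± 0.421 with vehicle (n = 3 each), a rise of 11.82 ± 0.273 (FDR = 1.81e-23). Il1b, a cytokine of the inflammasome pathway (chromosome 2, 129364570 to 129371139), rose by 10.10 ± 0.421 to 2645 ± 240 CPM. Clec4e, a receptor for damaged cells, rose by 10.48 ± 0.175 (FDR = 5.93e-26) and Clic5 by 11.10. Il12b reached 175 ± 27.6 CPM from 0.0288, and Upp1 259 from 0.0142. Trem2 fell (-4.62 ± 0.113, FDR = 5.96e-23), as did Rasgrp3 (-8.54 ± 0.172), Dkk2 (-8.52), Slco2b1 (-7.31), Cxcr4 (-6.61) and Rtn4rl1 (-6.43). Hpgd, which breaks down prostaglandins, fell from 66.8 ± 2.79 CPM to 0.

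The NF-kB targets and inflammatory cytokines rose as a group in APOE3 CV/CV. Of 45 tested, 44 rose and 0 fell, also when adjusted over the list alone, with a median of 4.69 (FDR = 6.73e-48, and 0.0309 with an estimated correlation). Il1rn rose by 6.92 ± 0.123, Sod2 by 4.99 and Tnf by 5.22. Of 52 interferon-stimulated genes 50 rose and 1 fell, the same counts as adjusted over the list alone (median 1.30, FDR = 3.14e-22, and 0.167 with an estimated correlation). Among them were Isg15 (2.60 ± 0.128, FDR = 2.06e-16), Ifit3 (1.59), Ifit1 (3.22), Oasl1 (3.70) and Cxcl10 (5.66 ± 0.161, from 73.6 to 3714 CPM). Ifnb1, the interferon itself (chromosome 4, 88522025 to 88522774), rose by 3.94 ± 0.221 (FDR = 3.87e-15).

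The cGAS-STING pathway, which senses DNA in the cytoplasm, split in this genotype: 7 of 19 members rose and 10 fell. Its median was -0.27, its mean 0.06 and its test pointed up without passing (FDR = 0.543). Mb21d1, the symbol of Cgas in the table, rose by 0.44 ± 0.0854 (FDR = 4.4e-05), Ikbke by 2.35 ± 0.0613, Tbk1 by 1.63 and Trim56 by 2.10. Tmem173, which encodes STING, fell (-0.31, FDR = 0.000379). Of 44 senescence and secretory genes 25 rose and 14 fell (median 0.88, FDR = 0.000618, and 0.167 with an estimated correlation). Mmp14 rose by 6.30, Mmp13 by 4.02 and Icam1 by 3.77, and the cell-cycle inhibitor Cdkn1a rose by 0.24 (FDR = 0.000727). Cdkn2a, the other inhibitor used to mark senescent cells, fell (-1.17), from 8.53 ± 0.339 to 3.80 ± 0.622 CPM (FDR = 2.57e-06).

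Homeostatic microglia genes fell with tau in APOE3 CV/CV. Of 33 tested, 23 fell and 4 rose (median -0.78, FDR = 2.74e-05, and 0.104 with an estimated correlation), with Mef2c at -2.97 and Csf1r at -1.30. P2ry12 fell (-0.27, FDR = 0.0384), a call that ended without replicate 2 or 3 of the vehicle group (FDR = 0.0967 and 0.075) or replicate 1 or 3 of the tau group (FDR = 0.0632 and 0.117). All 27 cholesterol synthesis genes fell (median -1.76, FDR = 9.33e-13, and 0.104 with an estimated correlation), such as Sqle at -3.43, Dhcr7 at -3.00 and Fads1 at -2.60 ± 0.092. Of 45 proliferation genes 40 fell and 3 rose (FDR = 1.72e-05, and 0.303 with an estimated correlation), among them Rrm2 (-4.02), Stmn1 (-3.31) and Top2a (-1.93), while Tpx2 rose by 2.18. Antigen presentation genes rose, 23 of 26 with 0 lower (FDR = 2.86e-09, and 0.104 with an estimated correlation), for example H2-Q6 (4.29) and Tap2 (1.88). Disease-associated genes moved both ways, 11 up and 21 down of 37 (FDR = 0.0417, and 0.425 with an estimated correlation). Cst7, 1 of them, rose by 3.99 ± 0.132, and Apoe fell (-1.28 ± 0.125, FDR = 5.77e-10). In all, 10112 genes passed, 4988 higher and 5124 lower, and 4672 of them changed more than 2-fold.

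In APOE3 R47H/CV tau raised 4896 genes and lowered 4940 of 9836 called. Nos2 rose by 11.43 to 2640 ± 721 CPM, Mir155hg reached 29.9 ± 5.07 CPM from 0, and Ifnb1 rose by 7.57 ± 0.265 (FDR = 1.11e-19). Gpr34, a receptor of resting microglia, fell (-6.49), as did Clec10a (-5.56 ± 0.148, 113.9 to 2.45 CPM), Cx3cr1 (-4.93) and Trem2 (-3.07 ± 0.108, FDR = 1.23e-19). P2ry12 rose here by 0.38 ± 0.106 (FDR = 0.0023), Mb21d1 by 0.62 (FDR = 3.79e-07), Cst7 by 4.39 ± 0.132, Cxcl10 by 5.97, Tnf by 5.55 and Il1b by 9.98 ± 0.433, and Apoe fell (-1.73 ± 0.121). All 52 interferon-stimulated genes rose (median 1.79, FDR = 5.6e-39, and 0.0452 with an estimated correlation), with Oasl1 at 5.13, Isg15 at 3.41 ± 0.133, Ifit3 at 2.57 and Usp18 at 3.54. The unfolded protein and integrated stress response rose as a group in this genotype, 23 of 31 up and 2 down (median 0.75, FDR = 2.78e-07, and 0.0419 with an estimated correlation), led by Asns (2.79), Ddit3 (2.57) and Hspa5 (1.67 ± 0.0587). NF-kB targets rose, 44 of 45 (FDR = 1.17e-40, and 0.0419 with an estimated correlation), as did antigen presentation, 23 of 26 (FDR = 1.27e-14, and 0.0419 with an estimated correlation). Cdkn1a rose by 0.56 (FDR = 2.35e-09), while Cdkn2a (-0.33, FDR = 0.0866) and Tmem173 (-0.09, FDR = 0.24) did not pass.

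In APOE4 CV/CV tau raised 5056 genes and lowered 5174 of 10230 called. Nos2 rose by 11.86 to 2055 ± 234 CPM, Il6 stood at 86.0 ± 13.9 CPM against 0.0324, Il12b at 89.7 against 0 and Adora2a at 34.6 against 0. Il1b rose by 7.05 ± 0.354 from a vehicle level of 10.1 ± 2.77 CPM. Rasgrp3 fell (-9.30), as did Slco2b1 (-7.59), Rtn4rl1 (-7.65), Nat8l (-7.01) and Trem2 (-4.61 ± 0.110, FDR = 3.16e-23). Cxcl10, a chemokine induced by interferon, rose by 7.11 ± 0.175, Isg15 by 3.01, Ifit3 by 2.10, Tnf by 5.05, Cst7 by 2.98 and Mb21d1 by 0.78 (FDR = 4.11e-09). Apoe fell (-1.39 ± 0.128), as did P2ry12 (-0.50, FDR = 0.000209) and Tmem173 (-0.34, FDR = 0.000101). Of 14 mitochondrially encoded genes 12 fell and 1 rose (median -0.99, FDR = 0.00338, and 0.529 with an estimated correlation), with mt-Nd1 at -1.87. Slc40a1, the iron exporter, fell (-3.69). Interferon-stimulated genes rose, 50 of 52 with 1 lower (median 1.48, FDR = 1.35e-26, and 0.186 with an estimated correlation), and NF-kB targets rose, 44 of 45 (median 4.54, FDR = 7.6e-42, and 0.0619 with an estimated correlation). Cdkn1a rose by 0.38 (FDR = 2.03e-06), and Cdkn2a fell to 2.08 ± 0.477 from 4.98 ± 0.537 CPM (FDR = 3.14e-06).

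In APOE4 R47H/CV tau raised 4721 genes and lowered 4894 of 9615 called. Tarm1, a receptor of myeloid cells, stood at 108 ± 12.2 CPM with tau and 0.0384 with vehicle, Il6 at 81.5 against 0.0259, Il12b at 84.4 against 0 and Mir155hg at 36.7 against 0.0130. Dkk2 fell (-8.06), as did Slco2b1 (-8.07), Rasgrp3 (-6.80), Cxcr4 (-5.21), the clock gene Dbp (-5.07) and Trem2 (-4.06 ± 0.117, FDR = 2.2e-21). Tmem173 fell (-0.98 ± 0.0714, FDR = 1.54e-12), as did Apoe (-2.21 ± 0.136, FDR = 3.43e-14), P2ry12 (-0.77, FDR = 3.88e-07) and Cdkn2a (-1.03, FDR = 9.39e-06). Il1b rose by 9.21 ± 0.404, Tnf by 5.63, Cxcl10 by 5.12, Isg15 by 2.22 ± 0.126, Ifit3 by 1.37, Cst7 by 1.57 ± 0.112 and Mb21d1 by 0.50 (FDR = 9.19e-06), while Cdkn1a did not change (-0.01, FDR = 0.947). Of 52 interferon-stimulated genes 50 rose and 1 fell (median 0.97, FDR = 1.05e-14, and 0.432 with an estimated correlation), and NF-kB targets rose, 44 of 45 (FDR = 4.71e-55, and 0.0203 with an estimated correlation). Cholesterol synthesis fell, with 18 down and 2 up of 27 (FDR = 0.000837, and 0.616 with an estimated correlation).

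Averaged over the 4 genotypes, tau changed 11988 genes, 5763 up and 6225 down. Clec4e rose by 9.05 ± 0.0792 (FDR = 4.38e-33), Nos2 by 11.07 ± 0.134, Il1b by 9.08 ± 0.202, Il1rn by 6.16, Mmp14 by 5.73, Ifnb1 by 4.58, Cxcl10 by 5.96, Tnf by 5.36, Cst7 by 3.23, Isg15 by 2.81 ± 0.0646, Ifit3 by 1.91 and Ikbke by 2.43 ± 0.0307. Rasgrp3 fell (-7.29 ± 0.0804), as did Dkk2 (-7.70), Nat8l (-5.77), Trem2 (-4.09 ± 0.0559, FDR = 9.05e-30) and Apoe (-1.65 ± 0.0638, FDR = 1.91e-19). Mb21d1 rose by 0.59 ± 0.0428 (FDR = 4.88e-13) and Cdkn1a by 0.29 ± 0.0293, while Tmem173 (-0.43), Cdkn2a (-0.95) and P2ry12 (-0.29) fell. The log2 changes of 14443 genes correlated between pairs of genotypes from 0.809 (APOE3 R47H/CV with APOE4 R47H/CV) to 0.923 (APOE3 CV/CV with APOE4 CV/CV). Among genes called in both of a pair, 94.9 to 99.6% moved the same way.

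NF-kB targets rose in the average, 44 of 45 (median 4.70, FDR = 6.79e-49, and 0.0872 with an estimated correlation). Immediate early genes rose too, 20 of 25 with 2 lower (median 1.33, FDR = 8.07e-08, and 0.159 with an estimated correlation); in APOE3 CV/CV Dusp1 rose by 4.38, Dusp2 by 7.47 and Atf3 by 1.73. NRF2 targets rose, 17 of 23 with 5 lower (FDR = 0.000398, and 0.516 with an estimated correlation), with Slc7a11 at 6.58 and Sqstm1 at 2.42 in APOE3 CV/CV. Glycolysis and hypoxia genes rose, 23 of 30 with 6 lower (FDR = 0.000398, and 0.516 with an estimated correlation), with Slc2a1 at 2.28 there. Ribosomal protein genes fell, 50 of 52 (median -0.70, FDR = 6.4e-08, and 0.516 with an estimated correlation), and mitochondrially encoded genes fell, 12 of 14 with 1 higher (FDR = 0.0427, and 0.648 with an estimated correlation). Lists that did not pass in the average included LXR targets (11 up, 12 down, FDR = 0.702), p53 targets (11 up, 14 down, FDR = 0.959), lysosome and phagocytosis genes (19 up, 25 down, FDR = 0.429), nuclear genes of oxidative phosphorylation (7 up, 50 down, FDR = 0.0836) and TGF-beta and matrix genes (10 up, 7 down, FDR = 0.398). In the p53 list Fas (4.59) and Gadd45b (3.72) rose and Sesn1 fell (-4.68) in APOE3 CV/CV.

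None of the 6 lists of markers of other cell types passed in the average of the tau effects. Of 6 endothelial markers 5 rose and 1 fell (median 1.93, FDR = 0.138). Border macrophage and monocyte markers split, 5 up and 9 down of 16 (FDR = 0.633), with Mrc1 at -3.39 and Vcan at 5.12 in APOE3 CV/CV. Of 11 astrocyte markers 5 rose and 2 fell, with a median of -0.20 but a mean of 0.46 and a test pointing up (FDR = 0.745). Oligodendrocyte lineage markers split 2 up and 6 down of 10 (FDR = 0.658), neuron markers 1 up and 2 down of 9 (FDR = 0.745), and fibroblast and mural markers 2 up and 5 down of 8 (FDR = 0.796). Of 5 sex-linked genes tau called 2 higher and 3 lower in APOE3 CV/CV and in APOE4 CV/CV, 2 higher and 1 lower in APOE3 R47H/CV and 0 in APOE4 R47H/CV, where 4 had no counts. In the average, which includes groups without counts, 0 passed.

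**Figure D1:**
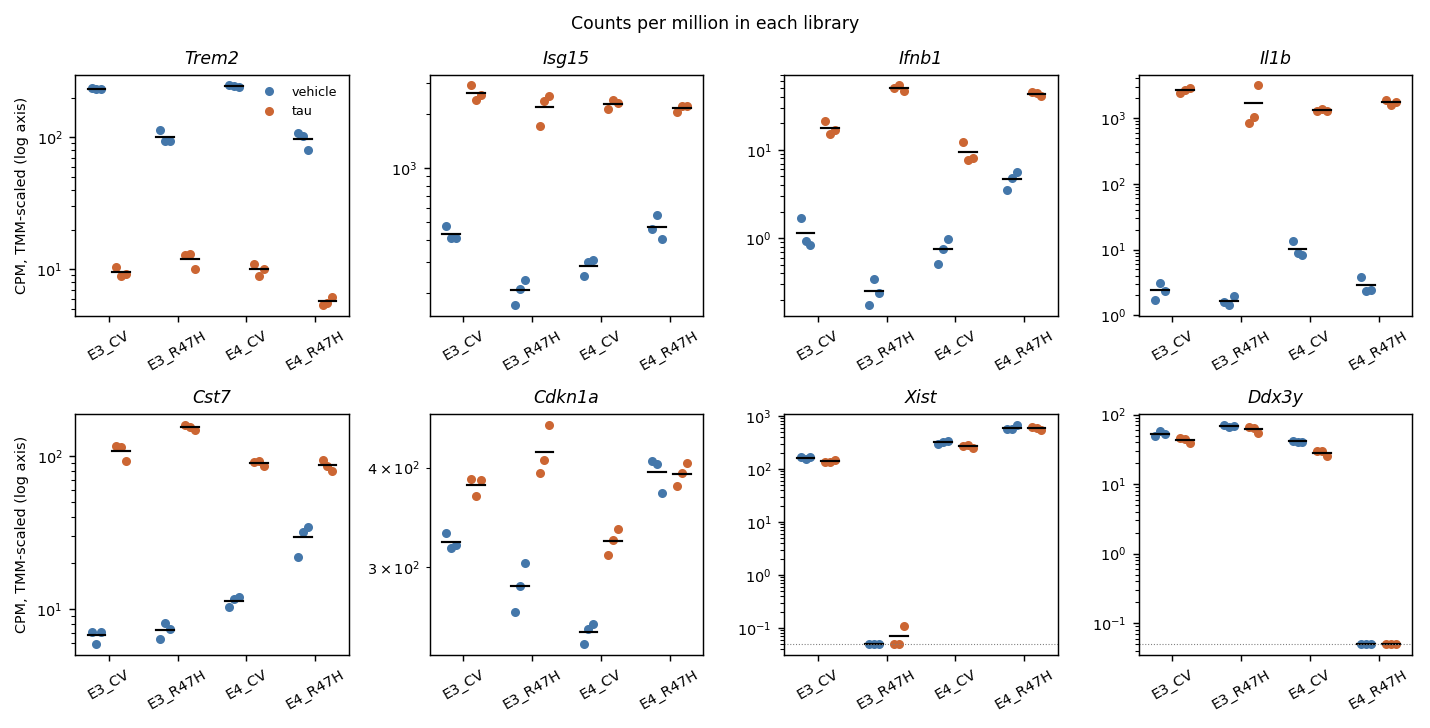
Levels of 8 genes in CPM. Each dot is a library and each bar the mean of a group, and levels under 0.05 are drawn at the dotted line.

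R47H in APOE3 under vehicle lowered interferon-stimulated genes (FDR = 4.55e-28, and 0.124 with an estimated correlation) and raised mitochondrial transcripts (FDR = 2.71e-12, and 0.0921 with an estimated correlation). Irf7, which drives interferon production, fell (-1.84 ± 0.0959, FDR = 4.16e-14), as did Oasl1 (-1.69), Isg15 (-1.05 ± 0.123, 431 ± 38.0 to 208 ± 32.7 CPM, n = 3 each, FDR = 1.46e-07), Ifit3 (-0.81 ± 0.0882) and Ifnb1 (-2.14 ± 0.458, FDR = 0.000662). Trem2 fell (-1.22 ± 0.088, FDR = 2.37e-11), and Apoe rose by 0.65 ± 0.111 (FDR = 4.53e-05). Mmp9, a matrix protease, rose from 3.82 ± 0.291 to 43.1 ± 6.44 CPM (FDR = 1.26e-15), and Gimap6 (17.1 against 0.548 CPM), Rbp4 (4.61), Ltc4s (3.63), Clec4e (3.32 ± 0.196) and Arg1 (2.93 ± 0.113, FDR = 9e-17) also rose. Cd72, an inhibitory receptor, fell from 358 ± 4.40 to 47.5 ± 4.32 CPM (FDR = 1.35e-18) and Slamf9 (-3.33 ± 0.181). This comparison called 4049 genes, 1895 higher and 2154 lower, with 671 over 2-fold.

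Of 52 interferon-stimulated genes 48 fell and 0 rose in that comparison, and 49 fell adjusted over the list alone (median -0.52, FDR = 4.55e-28, and 0.124 with an estimated correlation). Antigen presentation fell, 19 of 26 with 2 higher (FDR = 2.1e-10, and 0.0921 with an estimated correlation), as in H2-Q6 (-1.86 ± 0.164) and H2-T23 (-0.84). Mitochondrially encoded genes rose, 11 of 14 with 1 lower and 13 with 1 lower adjusted over the list alone (median 0.93, FDR = 2.71e-12, and 0.0921 with an estimated correlation), among them mt-Cytb (1.26 ± 0.107, FDR = 5.03e-10) and mt-Nd4 (1.10). The stress response fell, 14 of 31 with 6 higher (FDR = 0.00297, and 0.279 with an estimated correlation), with Asns at -2.02 ± 0.0953 and Chac1 at -3.90. Border macrophage markers rose, 8 of 16 with 3 lower (FDR = 7e-04, and 0.0921 with an estimated correlation), such as F13a1 (2.12 ± 0.180). NF-kB targets (17 up, 7 down, FDR = 0.00331, and 0.708 with an estimated correlation), senescence genes (13 up, 7 down, FDR = 0.0249, and 0.478 with an estimated correlation), glycolysis (15 up, 2 down, FDR = 0.0023, and 0.535 with an estimated correlation), NRF2 targets (11 up, 2 down, FDR = 0.00144, and 0.532 with an estimated correlation) and ribosomal proteins (25 up, 0 down, FDR = 4.97e-06, and 0.609 with an estimated correlation) were on balance higher. The cGAS-STING list did not pass (1 up, 5 down, FDR = 0.534). Tmem173 (-0.01, FDR = 0.957), Cdkn2a (0.10, FDR = 0.714), Il1b (-0.54, FDR = 0.576), Tnf (-0.68, FDR = 0.0549) and Cst7 (0.11, FDR = 0.66) did not pass. Cdkn1a was lower (-0.18, FDR = 0.019), but without replicate 1 of the CV/CV group FDR was 0.0756 and without replicate 1 of the R47H/CV group 0.0876. Mb21d1 (-0.24, FDR = 0.0399) lost its call without replicate 1 (0.191) or 3 (0.0677) of CV/CV or 1 (0.171) or 3 (0.163) of R47H/CV, Cxcl10 (-0.40, FDR = 0.0339) without replicate 1 (0.181) or 2 (0.0692) of CV/CV or 1 (0.257) of R47H/CV, and P2ry12 (0.36, FDR = 0.0115) without replicate 1 of CV/CV (0.0571). Of 5 sex-linked genes 4 were higher and 1, Xist, was lower.

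Under tau, R47H in APOE3 raised the stress response (FDR = 4.87e-08, and 0.0683 with an estimated correlation). Hspa5, a chaperone of the endoplasmic reticulum, rose by 1.09 ± 0.0579 (FDR = 4.7e-14), Phgdh by 1.97 ± 0.118, Gdf15 by 2.23 ± 0.110 (FDR = 1.3e-14), Vegfa by 2.55 ± 0.175, Gpr162 by 3.26 ± 0.217 (22.8 ± 6.11 against 2.33 CPM) and Ly6i by 2.77 ± 0.174. Ifnb1 rose by 1.49 ± 0.152 (FDR = 9.7e-09), P2ry12 by 1.01 ± 0.113 (FDR = 4.73e-08), Cst7 by 0.51 (FDR = 0.000263) and Cdkn2a by 0.94 ± 0.192 (FDR = 0.00026). The inhibitory cytokine Il10 fell (-2.29 ± 0.140, FDR = 6.99e-13), and Noct (-2.52 ± 0.155), Apoc1 (-2.43) and Il1rn (-1.74 ± 0.097, FDR = 1.3e-13) also fell. Isg15 (FDR = 0.104), Ifit3 (FDR = 0.145), Cxcl10 (FDR = 0.656), Apoe (FDR = 0.269), Cdkn1a (FDR = 0.0636), Tnf (FDR = 0.113) and Mb21d1 (FDR = 0.629) did not pass. There were 5793 genes called, 2914 higher and 2879 lower.

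Of 31 stress response genes 17 rose and 5 fell there (median 0.29, FDR = 4.87e-08, and 0.0683 with an estimated correlation). Mitochondrially encoded genes rose, 13 of 14 with 0 lower (median 0.72, FDR = 1.57e-07, and 0.338 with an estimated correlation), as did cholesterol synthesis, 14 of 27 with 0 lower (FDR = 0.000793, and 0.622 with an estimated correlation), ribosomal proteins, 39 of 52 (FDR = 8.94e-09, and 0.622 with an estimated correlation) and nuclear genes of oxidative phosphorylation, 32 of 67 with 1 lower (FDR = 0.00141, and 0.658 with an estimated correlation). NF-kB targets were lower, 20 of 45 with 9 higher (median -0.26, FDR = 0.00322, and 0.658 with an estimated correlation). Interferon-stimulated genes did not pass as a list (6 up, 16 down, FDR = 0.285). Trem2 was higher by 0.33 (FDR = 0.049), which ended without replicate 2 (FDR = 0.16) or 3 (FDR = 0.119) of the CV/CV group or replicate 1 (FDR = 0.162) or 2 (FDR = 0.175) of the R47H/CV group. Il1b was lower (-0.66, FDR = 0.0453), and the call ended without replicate 1, 2 or 3 of CV/CV (FDR = 0.0519, 0.0953 and 0.117) or replicate 1 or 2 of R47H/CV (FDR = 0.268 and 0.253). Tmem173 was higher (0.21, FDR = 0.0244), a call that ended without replicate 2 or 3 of CV/CV (0.0741 and 0.0631) or 1 of R47H/CV (0.144).

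R47H in APOE4 under vehicle raised interferon-stimulated genes, the reverse of its effect in APOE3. Cxcl10 rose by 1.88 ± 0.149 (18.7 ± 1.02 to 68.9 ± 15.3 CPM, FDR = 2.35e-10), Isg15 by 0.71 ± 0.122 (FDR = 5.96e-05), Ifit3 by 0.73 (FDR = 3.07e-07), Usp18 by 1.21 and Ifit1bl1 by 2.63 ± 0.176. Gbp2b, an interferon-induced GTPase (chromosome 3, 142594847 to 142619179), rose from 1.64 to 34.3 ± 6.87 CPM (FDR = 1.4e-14), Ly6a by 3.01 ± 0.168, Ccl5 by 2.71 and Ifnb1 by 2.56 ± 0.260 (FDR = 1.8e-08). Cst7 rose by 1.36 ± 0.124 (FDR = 2.71e-09), Cdkn1a from 249 ± 7.41 to 394.5 ± 19.9 CPM (FDR = 1.73e-09) Cdkn2a by 0.73 (FDR = 0.00138), P2ry12 by 0.51 (FDR = 0.000441) and Tmem173 by 0.25 (FDR = 0.00684). Trem2 fell (-1.34 ± 0.0878, FDR = 7.27e-12), as did F13a1 (-2.95 ± 0.192), Slco2b1 (-3.12), Fn1 (-1.61), Cd9 (-1.55) and Il1b (-1.76, FDR = 0.00219). Apoe (FDR = 0.513), Mb21d1 (FDR = 0.106) and Tnf (FDR = 0.245) did not pass. The comparison called 3546 genes, 1795 higher and 1751 lower.

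Of 52 interferon-stimulated genes 48 rose and 0 fell, and 50 rose adjusted over the list alone (median 0.54, FDR = 3.59e-40, and 0.0476 with an estimated correlation). Antigen presentation rose, 20 of 26 with 0 lower (median 0.49, FDR = 8.86e-20, and 0.00855 with an estimated correlation), led by H2-Q6 (2.16 ± 0.147) and H2-Q7 (2.02). Of 30 p53 targets 15 rose and 2 fell, and 16 rose with 6 lower adjusted over the list alone (FDR = 7.78e-05, and 0.00855 with an estimated correlation). Cholesterol synthesis fell, 20 of 27 with 0 higher (median -0.75, FDR = 2.23e-16, and 0.028 with an estimated correlation), as in Sqle (-1.53 ± 0.124) and Cyp51 (-1.39). Also lower were mitochondrially encoded genes, 11 of 14 (FDR = 5.89e-11, and 0.0896 with an estimated correlation), proliferation genes, 27 of 45 (FDR = 9.45e-09, and 0.125 with an estimated correlation), senescence genes, 16 of 44 (FDR = 0.000176, and 0.0896 with an estimated correlation) and disease-associated genes, 16 of 37 (FDR = 0.000361, and 0.125 with an estimated correlation), the last including Itgax (-1.24). Of 5 sex-linked genes 1, Xist, was higher and 4 were lower.

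With tau, R47H in APOE4 changed the fewest genes of all simple comparisons, 1297 with 601 higher and 696 lower. Ifnb1 rose by 2.19 ± 0.159 (9.39 ± 2.54 to 43.2 ± 2.59 CPM, FDR = 2.51e-10), Cd300e by 1.73, Tlr2 by 0.72, Cdkn1a by 0.28 (FDR = 0.00202) and Cdkn2a by 0.97 (FDR = 0.00387, but 0.053 without replicate 3 of R47H/CV). Cxcl9, a chemokine for T cells, fell from 78.8 ± 31.9 to 7.14 CPM (FDR = 5.53e-11), as did Mmp25 (-2.01 ± 0.179), Trem2 (-0.80 ± 0.140, FDR = 0.000326) and Tmem173 (-0.38, FDR = 0.000865), and Apoe fell to 6.72 ± 1.43 CPM (FDR = 0.00281). Glycolysis and hypoxia genes fell, 21 of 30 with 0 higher, and 23 adjusted over the list alone (median -0.41, FDR = 1.85e-27, and 0.0142 with an estimated correlation), with Ldha at -0.67 ± 0.0611, Pfkfb3 at -0.66, Pfkl at -0.65 and Bnip3 at -0.88. Only 1 interferon-stimulated gene passed, and Isg15 (FDR = 0.767), Ifit3 (FDR = 0.996), Cxcl10 (FDR = 0.714), Il1b (FDR = 0.401), Tnf (FDR = 0.634), P2ry12 (FDR = 0.224), Cst7 (FDR = 0.853) and Mb21d1 (FDR = 0.586) did not. The count depended on single libraries: 755 without replicate 2 and 716 without replicate 3 of CV/CV, 857 without replicate 2 and 851 without replicate 3 of R47H/CV, and 1206 at most. Fitted on its own 6 libraries this comparison called 1987 genes.

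Between APOE3 and APOE4 the R47H effects were compared across genes. Under vehicle their log2 changes correlated at -0.193, and of 1721 genes called in both 25.3% moved the same way. Under tau the correlation was 0.155, and of 845 genes called in both 77.8% moved the same way. The 10 genes that passed in all 4 R47H comparisons in the same direction and by at least 1.5-fold, a group chosen after seeing the data, included Slco2a1 (1.75, 2.55, 1.87 and 1.19 in APOE3 vehicle, APOE3 tau, APOE4 vehicle and APOE4 tau), Ly6i (1.04, 2.77, 0.85 and 0.62), Rasgrp1 (2.47, 0.64, 0.73 and 0.79) and St18 (0.85, 1.27, 0.73 and 1.12). Ear2 (-0.87, -2.93, -1.11 and -1.88), Noct (-2.07, -2.52, -1.30 and -0.83) and Slc24a3 (-1.41, -1.40, -1.03 and -0.78) were lower.

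APOE4 in CV/CV under vehicle lowered sterol synthesis and cell-cycle genes relative to APOE3. Scd2, a fatty acid desaturase, fell (-1.70 ± 0.102, FDR = 3.12e-12), as did Cyp51 (-1.05), Top2a (-1.14 ± 0.109, FDR = 2.4e-08), Stmn1 (-1.13) and Rrm2 (-1.49). Cxcl10 fell (-1.98 ± 0.150, 73.6 ± 10.1 to 18.7 ± 1.02 CPM, FDR = 2.48e-10), as did Isg15 (-0.60, FDR = 0.000823), Ifit3 (-0.69, FDR = 2e-06), Mb21d1 (-0.37 ± 0.0853, FDR = 0.00265), Cdkn1a (-0.37, FDR = 3.41e-05) and Cdkn2a (-0.77, FDR = 0.0013). Lilra6 (chromosome 7, 3908280 to 3915503) fell from 17.9 ± 1.91 to 0.223 CPM, Gbp2b from 45.6 ± 3.16 to 1.64 CPM, and the processed pseudogenes Rps3a3 (chromosome 13, 108670603 to 108671397) (-5.66 ± 0.144) and Rps3a2 (-5.31). C5ar2, a complement receptor (chromosome 7, 16234585 to 16244154), rose by 2.52 ± 0.154 (FDR = 3.35e-12), the scavenger receptor Marco by 2.23 ± 0.172, F13a1 by 1.87 ± 0.179, Pf4 by 1.32 ± 0.0799 (FDR = 3.14e-12), Cst7 by 0.75 (FDR = 0.000422) and Il1b by 2.04 ± 0.443 (FDR = 0.00143). Apoe (-0.32, FDR = 0.0505), Trem2 (0.07, FDR = 0.666), Tnf (FDR = 0.944), P2ry12 (FDR = 0.152) and Tmem173 (FDR = 0.596) did not pass. This comparison called 2697 genes, 1121 higher and 1576 lower, and without replicate 1 of APOE3 CV/CV 1699 passed (2225 at most in any other omission).

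Cholesterol synthesis fell, 25 of 27 with 0 higher, and 26 adjusted over the list alone (median -0.71, FDR = 1.77e-30, and 0.00838 with an estimated correlation). Proliferation genes fell, 38 of 45 with 0 higher, and 40 adjusted over the list alone (median -0.94, FDR = 3.84e-27, and 0.00838 with an estimated correlation). Of 30 p53 targets 14 fell and 2 rose (FDR = 0.000125, and 0.00838 with an estimated correlation), and of 23 LXR targets 11 fell and 1 rose (FDR = 1.23e-05, and 0.0118 with an estimated correlation). Interferon-stimulated genes fell, 28 of 52 with 1 higher, and 36 with 3 higher adjusted over the list alone (median -0.25, FDR = 2.03e-14, and 0.245 with an estimated correlation). Border macrophage markers rose, 5 of 16 with 1 lower (FDR = 0.000334, and 0.044 with an estimated correlation), and so did fibroblast and mural markers, 5 of 8 with 0 lower (median 2.07, FDR = 0.000145, and 0.0659 with an estimated correlation). Of 6 endothelial markers 3 fell (FDR = 0.000897, and 0.0118 with an estimated correlation). Of 5 sex-linked genes 1 rose and 4 fell.

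With tau, APOE4 in CV/CV lowered antioxidant and mitochondrial genes. Prdx1, a peroxide scavenger, fell (-1.12 ± 0.0669, FDR = 2.39e-12), as did Gstm1 (-1.64 ± 0.0959, FDR = 1.43e-12), Mgst1 (-0.94), Slc40a1 (-1.65), Fasn (-1.14) and mt-Nd6 (-1.10). Gbp2b fell from 575.5 ± 29.0 to 3.38 CPM (FDR = 1.55e-20), as did Lilra6 (-6.76) and Rps3a2 (-5.38). Tarm1 (chromosome 7, 3486500 to 3502624) rose by 4.60 ± 0.208 (5.71 to 142 ± 15.6 CPM) and Pirb by 1.93 ± 0.0697 (149 ± 5.79 to 567 ± 18.3 CPM, FDR = 1.71e-17). Il1b fell (-1.01 ± 0.263, FDR = 0.0083), as did Cxcl10 (-0.53, FDR = 0.00521), and Cdkn1a stood at 323 ± 12.2 against 381 ± 10.4 CPM (FDR = 0.006). Isg15 (FDR = 0.312), Ifit3 (FDR = 0.169), Trem2 (FDR = 0.757), Mb21d1 (FDR = 0.878), Tmem173 (FDR = 0.415), Tnf (FDR = 0.65), P2ry12 (FDR = 0.974) and Cst7 (FDR = 0.0943) did not pass. Apoe was lower (-0.43, FDR = 0.0356), but not without replicate 1 (0.0701) or 3 (0.182) of APOE3 or 1 (0.169) or 2 (0.0705) of APOE4, and Cdkn2a was lower (-0.88, FDR = 0.00716), but not without replicate 1 of APOE3 (0.0565) or 1 of APOE4 (0.062). There were 2336 genes called, 898 higher and 1438 lower.

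Of 23 NRF2 targets 18 fell and 0 rose there, and 20 fell adjusted over the list alone (median -0.66, FDR = 5.37e-33, and 0.0114 with an estimated correlation). Mitochondrially encoded genes fell, 12 of 14 (median -1.05, FDR = 1.95e-26, and 0.0114 with an estimated correlation), and LXR targets fell, 9 of 23 with 1 higher (FDR = 6.95e-05, and 0.0443 with an estimated correlation). Lysosome and phagocytosis genes fell, 21 of 46 with 1 higher (median -0.16, FDR = 9.18e-07, and 0.0896 with an estimated correlation), as in Ctsd (-0.65), and disease-associated genes fell, 17 of 37 with 4 higher (FDR = 2.03e-05, and 0.0896 with an estimated correlation). Fibroblast and mural markers were higher, 4 of 8 (FDR = 0.000143, and 0.0983 with an estimated correlation).

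APOE4 in R47H/CV differed from APOE3 in more genes than in CV/CV: 7079 under vehicle, 3555 higher and 3524 lower. In R47H/CV the APOE3 samples held next to no Xist and the APOE4 samples no counts at the Y-linked genes. The CV/CV groups of both APOE forms held both, so the larger count cannot be assigned to APOE4. Soat2, which esterifies cholesterol, rose by 6.29 ± 0.238 (0.289 to 22.9 ± 1.48 CPM), Slamf9 by 5.26 ± 0.178, H2-Q6 by 4.96 ± 0.173 (15.8 ± 2.05 to 490.2 ± 76.6 CPM), Trib3 by 4.80 ± 0.152, Asns by 3.48 ± 0.0914 (FDR = 2.96e-21) and Irf7 by 2.89 ± 0.0996 (FDR = 1.06e-18). Ifnb1 rose by 4.13 ± 0.345, Isg15 by 1.17 ± 0.123 (FDR = 7.74e-09), Ifit3 by 0.85, Cst7 from 7.31 ± 0.872 to 29.4 ± 6.75 CPM and Cdkn1a by 0.47 ± 0.0586 (FDR = 1.24e-07). Rbp4 fell (-7.18 ± 0.407), as did Fn1 (-3.87 ± 0.152), Arg1 (-2.93), mt-Cytb (-2.82 ± 0.113, FDR = 1.83e-17), Itgax (-2.14) and Apoe (-0.85 ± 0.111, FDR = 3.58e-07). Trem2 (FDR = 0.616), Mb21d1 (FDR = 0.603), Cdkn2a (FDR = 0.496), Il1b (FDR = 0.261), Tnf (FDR = 0.375) and Cxcl10 (FDR = 0.081) did not pass. P2ry12 was higher (0.37, FDR = 0.00387, but 0.054 without replicate 3 of APOE4), as was Tmem173 (0.20, FDR = 0.0191, but 0.106 without replicate 1 of APOE3 and 0.0576 without replicate 3 of APOE4).

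Of 52 interferon-stimulated genes 48 rose and 0 fell in that comparison, and 50 rose adjusted over the list alone (median 0.81, FDR = 2.1e-26, and 0.0986 with an estimated correlation). Antigen presentation rose, 21 of 26 with 2 lower (median 0.78, FDR = 1.57e-19, and 0.0114 with an estimated correlation). Mitochondrially encoded genes fell, 13 of 14 with 1 higher (median -2.02, FDR = 2e-21, and 0.0155 with an estimated correlation), and cholesterol synthesis fell, 25 of 27 (median -1.25, FDR = 1.91e-18, and 0.0155 with an estimated correlation). Proliferation genes fell, 43 of 45 with 2 higher (median -1.31, FDR = 5.77e-13, and 0.0752 with an estimated correlation), and ribosomal proteins fell, 44 of 52 (FDR = 9.37e-10, and 0.351 with an estimated correlation). The stress response split, 14 up and 13 down of 31, with a median of -0.11 but a mean of 0.48 and a test pointing up (FDR = 0.0081, and 0.259 with an estimated correlation). Of 5 sex-linked genes 1 rose and 4 fell.

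Under tau the APOE4 effect in R47H/CV covered 7212 genes, 3426 higher and 3786 lower. Phgdh, which starts serine synthesis, fell (-3.06 ± 0.127), as did Hspa5 (-1.58 ± 0.0586, FDR = 8.14e-18), Herpud1 (-2.09), Prdx1 (-2.18 ± 0.069, FDR = 2.45e-19), Gstm1 (-2.51), Vegfa (-2.28), Scd2 (-2.71) and mt-Cytb (-2.67). Trem2 fell (-1.05 ± 0.139, FDR = 4.1e-07), as did Apoe (-1.33 ± 0.146, FDR = 1.79e-08), Cst7 (-0.83, FDR = 2.32e-07), P2ry12 (-0.78, FDR = 1.01e-06), Cxcl10 (-0.56, FDR = 0.000845), Ifit3 (-0.35, FDR = 0.00161), Tmem173 (-0.69, FDR = 1.05e-08) and Cdkn2a (-0.85, FDR = 0.000378). Gbp2b fell from 677 ± 70.2 to 6.01 CPM. Ccr3 rose by 4.48 ± 0.228, C5ar2 by 3.49 ± 0.198, P2ry6 by 1.61 and Cd74 by 1.28. Isg15 (FDR = 0.888), Il1b (FDR = 0.876), Cdkn1a (FDR = 0.209), Tnf (FDR = 0.0694) and Mb21d1 (FDR = 0.572) did not pass.

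The stress response fell there, 21 of 31 with 5 higher, and 22 with 6 higher adjusted over the list alone (median -0.40, FDR = 5.04e-13, and 0.00397 with an estimated correlation). Mitochondrially encoded genes fell, 13 of 14 with 1 higher (median -2.22, FDR = 7.83e-27, and 0.00645 with an estimated correlation), and LXR targets fell, 16 of 23 with 3 higher (FDR = 0.000214, and 0.042 with an estimated correlation). NRF2 targets were lower, 19 of 23 with 2 higher (FDR = 1.88e-14, and 0.0686 with an estimated correlation), as were cholesterol synthesis, 16 of 27 (FDR = 6.47e-07, and 0.221 with an estimated correlation), and nuclear genes of oxidative phosphorylation, 41 of 67 (FDR = 1.5e-05, and 0.474 with an estimated correlation). Between CV/CV and R47H/CV the APOE4 effects correlated at 0.267 under vehicle and 0.434 under tau. Of 2032 and 1887 genes called in both, 73.6% and 96.0% moved the same way.

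**Figure D2:**
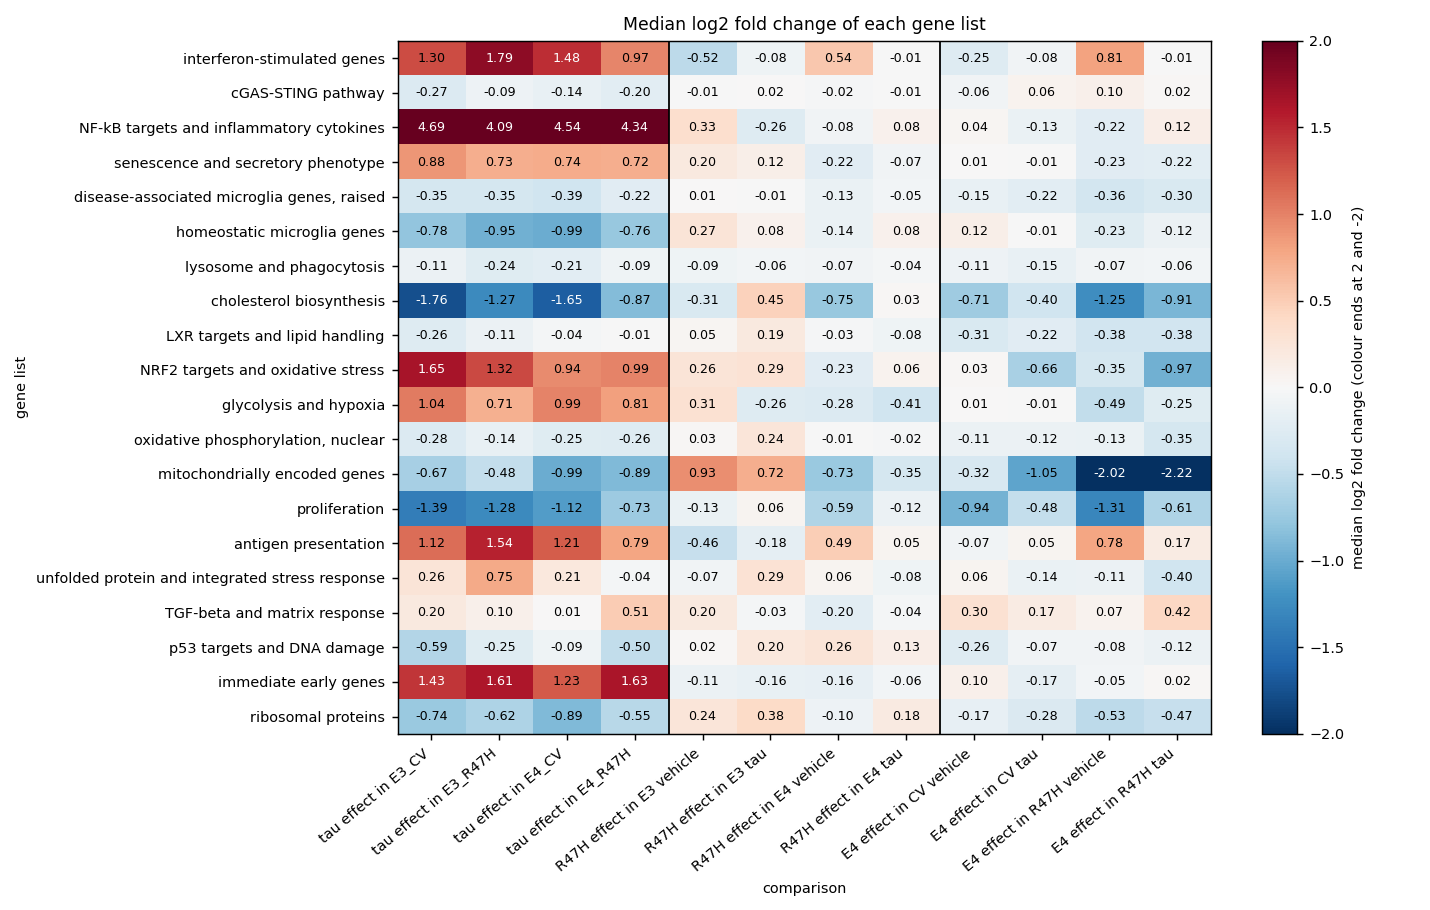
Median log2 fold change of 20 gene lists in the 12 simple comparisons.

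The response to tau was compared between R47H/CV and CV/CV groups, which also differ in the sex-linked genes. In APOE3 the response differed in 3625 genes, 1945 more positive and 1680 more negative in R47H/CV. Phgdh (2.30 ± 0.165, FDR = 7.1e-11), Asns (1.55 ± 0.124), Ddit3 (1.19 ± 0.118) and Hspa5 (1.08 ± 0.0812) responded more strongly, and 21 of 31 stress response genes did so with 0 the other way (median 0.57, FDR = 1.23e-15, and 0.00277 with an estimated correlation). Ifnb1 (3.63 ± 0.469), Irf7 (1.55 ± 0.132), Isg15 (0.80 ± 0.172, FDR = 0.000786) and Ifit3 (0.98) also rose more, with 32 of 52 interferon-stimulated genes (FDR = 0.448 with an estimated correlation). Isg15 and Ifit3 were lower in R47H/CV under vehicle and not called under tau, so their differences lay mainly in the vehicle levels. Ifnb1 was lower under vehicle, with 4 to 8 counts per library in APOE3 R47H/CV, and higher under tau. Trem2 fell less, with a difference of 1.55 ± 0.159 (FDR = 3.08e-08). In APOE4 the response differed in 1756 genes, 792 more positive and 964 more negative. Cxcl9 (-5.22 ± 0.511), Cxcl10 (-1.99 ± 0.198, FDR = 6.77e-08), Gbp2 (-1.81), Cmpk2 (-1.72 ± 0.170), H2-Q6 (-1.94 ± 0.200) and Cst7 (-1.41 ± 0.163) responded less in R47H/CV, with 45 of 52 interferon-stimulated genes lower (median -0.58, FDR = 0.0652 with an estimated correlation). Il1b rose more there (2.17 ± 0.494, FDR = 0.0032). Between these APOE4 groups Cxcl10, Cst7 and Il1b were called under vehicle and not under tau, so their differences lay mainly in the vehicle levels.

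The response to tau differed between APOE4 and APOE3 in 751 genes in CV/CV, 326 more positive and 425 more negative, a count that was 472 without replicate 1 of APOE3 CV/CV vehicle and 704 at most in other omissions. Cxcl10 rose more (1.45 ± 0.198, FDR = 2.61e-05), and Il1b (-3.05 ± 0.513, FDR = 0.000375), Marco (-2.65 ± 0.232), Ednrb (-2.97 ± 0.170), Prdx1 (-0.89 ± 0.0938), Gstm1 (-1.28) and Slc40a1 (-2.02 ± 0.184) rose less or fell further. NRF2 targets were lower, 15 of 23 with 0 higher (median -0.70, and FDR = 0.00949 with an estimated correlation), and so were 9 of 31 stress response genes (median -0.16, and FDR = 0.0327 with an estimated correlation). In R47H/CV 4748 genes differed, 2065 more positive and 2683 more negative. Phgdh (-4.38 ± 0.169, FDR = 1.22e-16), Trib3 (-4.17), Asns (-2.80 ± 0.120), Irf7 (-2.37 ± 0.133), H2-Q6 (-3.70), Ifnb1 (-4.34 ± 0.382) and Cst7 (-2.83 ± 0.171) responded less in APOE4, and Fam43a (5.30 ± 0.257), Gimap6 (5.19 ± 0.287) and Gpr34 (4.41 ± 0.475) were less lowered or more raised. Trib3, Asns, Irf7, H2-Q6, Ifnb1 and Cst7 were higher in APOE4 R47H/CV under vehicle, so their differences lay at least partly in the vehicle levels. Of 31 stress response genes 25 were lower with 0 higher (median -0.66, and FDR = 0.000159 with an estimated correlation).

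The remaining genes that were always named gave these differences. For tau by R47H in APOE3, Cdkn1a (0.32, FDR = 0.00459) and P2ry12 (0.65, FDR = 0.00232) passed, Cdkn2a (0.84, FDR = 0.0131) passed but not without replicate 3 of R47H/CV tau (0.054), and Apoe (FDR = 0.0586), Mb21d1 (FDR = 0.315), Tmem173 (FDR = 0.125), Cxcl10 (FDR = 0.253), Il1b (FDR = 0.929), Tnf (FDR = 0.496) and Cst7 (FDR = 0.13) did not. In APOE4, Apoe (-0.82, FDR = 0.00345), Tmem173 (-0.63, FDR = 5.95e-05), Cdkn1a (-0.38, FDR = 0.00196), Isg15 (-0.79, FDR = 0.00196) and Ifit3 (-0.73, FDR = 0.000131) passed. Mb21d1 (FDR = 0.132), Cdkn2a (FDR = 0.659), Tnf (FDR = 0.236) and P2ry12 (FDR = 0.308) did not pass there, and Trem2 (0.54, FDR = 0.0307) lost its call in 7 omissions (0.0512 to 0.125). For tau by APOE4 in CV/CV, Ifit3 (0.51, FDR = 0.0127) and Cst7 (-1.02, FDR = 0.000654) passed, and Apoe (FDR = 0.815), Trem2 (FDR = 0.988), Mb21d1 (FDR = 0.105), Tmem173 (FDR = 0.916), Cdkn1a (FDR = 0.404), Cdkn2a (FDR = 0.901), Isg15 (FDR = 0.194), Tnf (FDR = 0.822) and P2ry12 (FDR = 0.483) did not. In R47H/CV, Trem2 (-0.99, FDR = 2.5e-05), Tmem173 (-0.88, FDR = 6.85e-08), Cdkn1a (-0.56, FDR = 4.17e-06), Isg15 (-1.19, FDR = 3.21e-06), Ifit3 (-1.20, FDR = 1.33e-08), Cxcl10 (-0.86, FDR = 0.000909) and P2ry12 (-1.15, FDR = 6.88e-07) passed, and Mb21d1 (FDR = 0.478), Il1b (FDR = 0.397) and Tnf (FDR = 0.887) did not. Apoe (-0.48, FDR = 0.0449) lost its call there in 8 omissions (0.0538 to 0.159) and Cdkn2a (-0.71, FDR = 0.0263) in 6 (0.0515 to 0.109).

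The R47H effect itself differed between the APOE3 and APOE4 groups, which also differ in the sex-linked genes. Under vehicle it differed in 4361 genes, 2244 more positive and 2117 more negative in APOE4. All 52 interferon-stimulated genes were more positive (median 1.13, FDR = 5.59e-52, and 0.0227 with an estimated correlation), as in Irf7 (2.63 ± 0.133), Oasl1 (2.85), Isg15 (1.76 ± 0.173, FDR = 5.25e-09) and Cxcl10 (2.28 ± 0.204), and so were 20 of 26 antigen presentation genes with 2 the other way (median 0.95, and FDR = 0.0062 with an estimated correlation). Mitochondrially encoded genes were more negative, 13 of 14 (median -1.76, and FDR = 0.0227 with an estimated correlation), and border macrophage markers too, 9 of 16 with 3 the other way (median -0.87, and FDR = 0.0227 with an estimated correlation), such as F13a1 (-5.06 ± 0.263), Arg1 (-3.03) and Stab1 (-2.01). Cdkn1a was more positive (0.85 ± 0.0829, FDR = 4.73e-09), and Trem2 did not differ (-0.12, FDR = 0.493). Under tau 3504 genes differed, 1887 more positive and 1617 more negative, with Hspa5 (-1.23 ± 0.0813), Herpud1 (-1.58 ± 0.139), Phgdh (-2.48) and Trem2 (-1.13 ± 0.193, FDR = 7.91e-05) more negative and 16 of 31 stress response genes lower (median -0.45, and FDR = 0.00325 with an estimated correlation). Across treatment, TREM2 and APOE together 2866 genes differed, 1294 more positive and 1572 more negative. Stress response (20 of 31 lower, median -0.57, and FDR = 0.00495 with an estimated correlation) and antigen presentation (19 of 26 lower, median -0.87, and FDR = 0.0393 with an estimated correlation) were among them, with Isg15 at -1.60 ± 0.243, while 45 of 52 interferon-stimulated genes were lower (FDR = 0.0519 with an estimated correlation).

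For R47H by APOE4 in vehicle Apoe (-0.53, FDR = 0.0109), Mb21d1 (0.43, FDR = 0.00729), Ifit3 (1.54, FDR = 1.37e-10) and Cst7 (1.25, FDR = 1.62e-05) also passed, and Il1b (FDR = 0.252), Tnf (FDR = 0.638) and P2ry12 (FDR = 0.509) did not. Tmem173 (0.26, FDR = 0.0434) lost its call in 9 omissions (0.0554 to 0.0913) and Cdkn2a (0.63, FDR = 0.0372) in 8 (0.0623 to 0.102). Under tau Apoe (-0.90, FDR = 0.00164), Tmem173 (-0.59, FDR = 0.000106), P2ry12 (-0.77, FDR = 0.00074) and Cst7 (-0.56, FDR = 0.00628) passed. Mb21d1 (FDR = 0.876), Cdkn1a (FDR = 0.227), Cdkn2a (FDR = 0.96), Isg15 (FDR = 0.535), Ifit3 (FDR = 0.372), Cxcl10 (FDR = 0.954) and Tnf (FDR = 0.129) did not pass, and Il1b (FDR = 0.0352) lost its call in 9 omissions (0.051 to 0.114). Across all 3 factors Trem2 (-1.01, FDR = 0.00186), Tmem173 (-0.85, FDR = 5.36e-05), Cdkn1a (-0.70, FDR = 5.21e-05), Ifit3 (-1.71, FDR = 4.54e-08), Cxcl10 (-2.30, FDR = 4.82e-07), P2ry12 (-0.92, FDR = 0.00283) and Cst7 (-1.81, FDR = 3.99e-06) passed, and Apoe (FDR = 0.364), Mb21d1 (FDR = 0.0557), Cdkn2a (FDR = 0.298), Il1b (FDR = 0.0608) and Tnf (FDR = 0.754) did not.

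**Figure D3:**
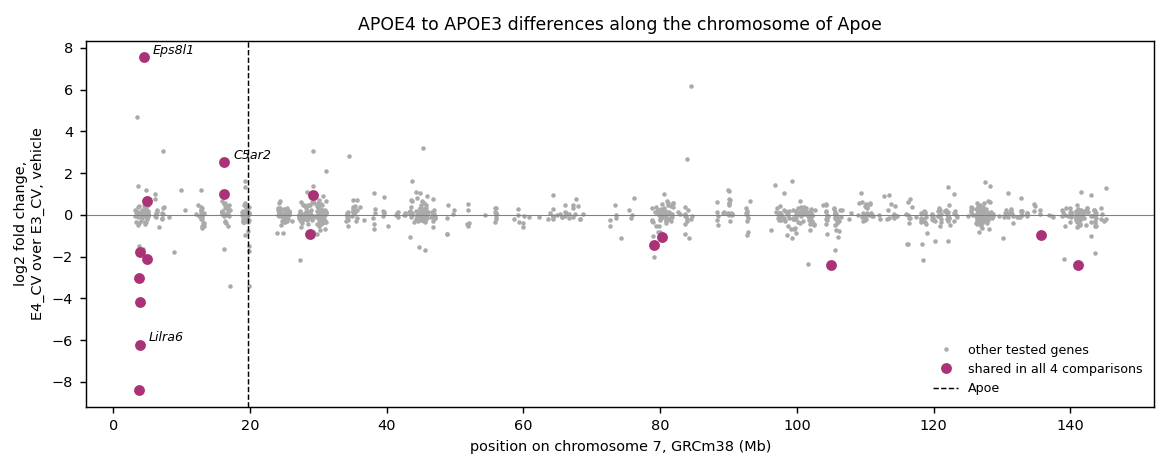
Change with APOE4 of genes along the chromosome that carries Apoe, in CV/CV under vehicle. Genes that passed in all 4 comparisons of APOE4 with APOE3, in the same direction and by more than 1.5-fold, are marked.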

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

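The tests of the APOE and Trem2 patterns below, and the sorting of the splits by kind, were chosen after the results were seen. The differences between effects were planned before the data were examined.

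R47H moved interferon-stimulated genes down in APOE3 (FDR = 4.55e-28, and 0.124 with an estimated correlation) and up in APOE4 under vehicle, where Xist moved the same ways. Of 1667 genes called in both comparisons and not placed on the X or Y chromosome 1240 (74.4%) moved in opposite directions. Xist varied by 5.71 to 11.6% among replicates of the 6 groups that express it, so the libraries of a group were alike in sex makeup. Replicates drawn from a single pool of cells per genotype would look the same, and whether they were is not given. In that case the FDR values of genotype comparisons cover only the spread within pools and not that between animals. Whether sex makeup, or a litter or culture effect of each genotype, accounts for the opposite effects was not tested, because both differ with the groups compared.

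APOE4 and APOE3 differed in 144 genes in all 4 comparisons in the same direction and by more than 1.5-fold, 36 higher and 108 lower in APOE4. Such genes were denser within 20 Mb of Apoe, 12 of 394 (3.05%) against 131 of 13926 elsewhere (0.941%, odds ratio 3.31, Fisher's exact p = 0.000591), as Lilra6 (-6.23, -6.76, -4.56 and -6.08) and Eps8l1 (5.53 to 6.35 CPM in APOE4 groups, 0.0215 to 0.0988 in APOE3 groups). With neighbouring genes of this kind counted once this fell to 7 of 389 (1.80%, odds ratio 2.16, Fisher's exact p = 0.0848), so a segment of chromosome carried along with the allele may account for part of them but is not shown. Pseudogenes were also over-represented, 17 of 841 (2.02%, odds ratio 2.19, Fisher's exact p = 0.00598), as Rps3a2 and Rps3a3. However, 7 of the 17 lie side by side on chromosome 1 (24611535 to 24616197), and with neighbours counted once 11 of 835 remained (1.32%, odds ratio 1.56, Fisher's exact p = 0.175), which leaves reads shared with near-identical copies open. The 144 genes include 12 on the X and Y chromosomes, among them Xist (0.97 and 0.92), Eif2s3y (-0.74 and -0.69) and Uty (-0.60 and -0.63) in CV/CV vehicle and tau. In R47H/CV Xist was at 596.9 and 579.5 CPM in APOE4 vehicle and tau, against 0 and 0.0363 in APOE3. Eif2s3y (50.8 and 69.2 CPM) and Uty (34.7 and 46.1 CPM) in APOE3 R47H/CV vehicle and tau stood against 0 in APOE4 R47H/CV. Sex makeup thus differed in the same direction in all 4 comparisons, and its part in the other genes was not tested.

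Trem2 counts were lower in R47H/CV under vehicle in both APOE backgrounds. A fixed share of R47H reads left uncounted would give the same R47H effect under tau, but in APOE3 the effects differed by 1.55, which speaks against it as the only cause there. In APOE4 the effect was -1.34 under vehicle and -0.80 under tau, and the difference of 0.54 (FDR = 0.0307) lost its call in 7 of the 12 omissions of a library, so the argument is weaker there. Fewer microglia among the cells would lower other homeostatic genes as much, but their medians were 0.27 in APOE3 and -0.14 in APOE4, with lower quartiles of -0.12 and -0.48. Both facts leave regulation of Trem2 itself possible, which these counts cannot separate from linked sequence differences.

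Effects differed between groups in 3625 genes (tau by R47H in APOE3), 1756 (tau by R47H in APOE4), 751 (tau by APOE4 in CV/CV), 4748 (tau by APOE4 in R47H/CV), 4361 (R47H by APOE4 in vehicle), 3504 (R47H by APOE4 in tau) and 2866 (all 3 factors). For stress response genes the median difference was 0.57 for tau by R47H in APOE3, -0.16 and -0.66 for tau by APOE4 in CV/CV and R47H/CV, -0.45 for R47H by APOE4 in tau and -0.57 for all 3 factors. NRF2 targets stood at -0.70 for tau by APOE4 in CV/CV. For R47H by APOE4 in vehicle interferon-stimulated genes stood at 1.13, mitochondrially encoded genes at -1.76, antigen presentation at 0.95 and border macrophage markers at -0.87, and antigen presentation stood at -0.87 for all 3 factors.

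Single genes differed as follows. Tau by R47H in APOE4 gave Cxcl10 -1.99, Il1b 2.17 and Cst7 -1.41, and tau by APOE4 in CV/CV gave Cxcl10 1.45, Il1b -3.05 and Cst7 -1.02. Tau by APOE4 in R47H/CV gave Isg15 -1.19, Ifit3 -1.20, P2ry12 -1.15 and Cst7 -2.83. R47H by APOE4 gave Isg15 1.76, Ifit3 1.54, Cxcl10 2.28 and Cst7 1.25 in vehicle and Trem2 -1.13 and Il1b 1.07 in tau. The Il1b call (FDR = 0.0352) ended in 9 omissions, without replicate 2 or 3 of APOE3 CV/CV tau (0.0622 and 0.0726), 1 or 2 of APOE3 R47H/CV tau (0.0805 and 0.114), 1, 2 or 3 of APOE4 CV/CV tau (0.0672, 0.051 and 0.0665) or 1 or 3 of APOE4 R47H/CV tau (0.0748 and 0.0576). All 3 factors together gave Trem2 -1.01, Isg15 -1.60, Ifit3 -1.71, Cxcl10 -2.30 and Cst7 -1.81.

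Splits of the same libraries were compared with the real groups. For each of 12 simple comparisons the real groups called the most genes, 1 of 10 splits, with at most 2 genes in any other, but 10 splits are too few for a share under 0.05. Every other such split also mixed libraries of both groups, which widens the spread within its groups. Low counts in these splits were therefore likely from the start. The averaged tau effect (11988 against at most 9106), tau by APOE4 in R47H/CV (4748 against 4631) and all 3 factors (2866 against 2615) ranked at 1 of 100. The split with 9106 genes exchanged most libraries of every pair, so it nearly repeats the mirror of the real groups. Those with 4631 and 2615 genes kept most libraries of 1 pair and exchanged most of another, a kind discussed below. These ranks therefore do not measure chance. Tau by R47H in APOE3 was reached in 3 of 100 splits (highest 6099), tau by R47H in APOE4 in 5 (3234), tau by APOE4 in CV/CV in 7 (1198), R47H by APOE4 in vehicle in 6 (6425) and in tau in 7 (6914), the real split included. By these counts the share was under 0.05 for tau by R47H in APOE3 and not for the last 4. However, 21 of the 23 other splits that reached the real count kept most of the libraries of 1 pair of groups and exchanged those of another. This adds the effects of the pairs in place of subtracting them, so such splits do not measure chance for a difference. The highest of the remaining splits gave 2643, 1315, 361, 4411 and 4159 genes in the order above, so only the R47H by APOE4 counts (4361 and 3504) were exceeded by a split of that kind. Each of these highest splits kept, or exchanged, all libraries of 1 pair and most of the other. They nearly repeat the real groups or their mirror and do not measure chance either. For all comparisons named here the splits therefore do not settle whether an arbitrary grouping could give the counts.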

How the results depend on the processing

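All 20 counts of called genes stayed within 1.5 times of their value under RLE scaling, DESeq2, no filter and the replicate block. All 10 counts of genotype comparisons also did so without genes on the X and Y chromosomes, an alternative added after seeing the data. That removal left 13987 genes, so a large move of a count was unlikely from the start. It cannot show whether sex makeup changed genes on other chromosomes. RLE scaling moved the median of all genes by -0.02 to 0.02 on the log2 scale. RLE scaling and DESeq2 also take most genes as unchanged, so they do not test that premise of TMM. With only its own 6 libraries, R47H in APOE4 tau called 1987 genes in place of 1297. Leaving out a library moved 6 of 192 counts by more than that factor: R47H in APOE4 tau fell to 755 and 716 without replicates 2 and 3 of APOE4 CV/CV tau and to 857 and 851 without replicates 2 and 3 of APOE4 R47H/CV tau (1206 at most, without replicate 1 of APOE4 CV/CV tau). APOE4 in CV/CV vehicle fell to 1699 and the difference of tau responses by APOE4 in CV/CV to 472, both without replicate 1 of APOE3 CV/CV vehicle (at most 2225 without replicate 1 of APOE4 CV/CV and 704 without replicate 1 of APOE3 CV/CV tau). Of 2249 calls on named genes, 2244 were the same under RLE scaling, 2210 without the filter and 2226 with the block, and 2227 of 2244 under DESeq2, with 0 reversed. Of 21330 calls in leave-one-out fits 20883 were the same, 419 were lost and 28 gained. Of 540 list tests 238 were called, and with the estimated correlation 43 of these stayed called and 195 lost their call. Under fry 386 of the 540 were the same, with 127 stronger, 26 weaker and 1 reversed. The reversed one was the p53 list in the averaged tau effect, up by fry (FDR = 6.14e-05) with a median below 0. Without the filter the test of the sex-linked list turned up, with FDR = 0.0418 for R47H in APOE3 vehicle and FDR = 0.0513 for R47H in APOE3 tau. Over the 7835 genes with a mean of at least 10 CPM the tau responses correlated at 0.879 to 0.977 between genotypes, and the R47H effects of APOE3 and APOE4 at -0.269 in vehicle and 0.138 in tau. No pairing by replicate number was seen: deviations of samples of the same genotype and number correlated at -0.0479 to 0.0445, with 0 of 12 pairs over 0.1. Between genotypes the range was -0.115 to 0.113 for the same number (1 of 72 pairs over 0.1). It was -0.119 to 0.101 for different numbers (1 of 144). Whether samples of the same number were prepared together cannot be told from these values. As a block the number gave 9858 genes for tau in APOE3 CV/CV, 533 for the difference by APOE4 in CV/CV and 2485 for the difference by all 3 factors.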

Other observations

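Some lists moved in comparisons not yet described. R47H in APOE4 with tau raised ribosomal proteins, 14 of 52 with 0 lower (FDR = 2.29e-09, and 0.429 with an estimated correlation), and lowered mitochondrially encoded genes, 5 of 14 (FDR = 2.84e-05, and 0.343 with an estimated correlation) and stress response genes, 6 of 31 with 1 higher (FDR = 0.0033, and 0.276 with an estimated correlation). Of 16 border macrophage and monocyte markers 6 fell there, among them Pf4 (-0.94) and Vcan (-0.81), and 2 rose (FDR = 0.00728, and 0.265 with an estimated correlation). Homeostatic genes were on balance higher, 6 of 33 with 2 lower (FDR = 0.0286, and 0.35 with an estimated correlation). In APOE4 under vehicle R47H also lowered glycolysis genes, 15 of 30 with 1 higher (FDR = 8.48e-05, and 0.268 with an estimated correlation), TGF-beta and matrix genes, 7 of 20 with 1 higher (FDR = 0.0134, and 0.22 with an estimated correlation), and homeostatic genes, 11 of 33 with 7 higher (FDR = 0.00768, and 0.19 with an estimated correlation), with Gpr34 among the strongest.

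APOE4 in CV/CV with tau lowered cholesterol synthesis, 10 of 27 with 1 higher (median -0.40, FDR = 4.16e-08, and 0.135 with an estimated correlation), ribosomal proteins, 28 of 52 with 1 higher (FDR = 3.23e-10, and 0.371 with an estimated correlation), and proliferation genes, 17 of 45 with 1 higher (FDR = 2.73e-05, and 0.289 with an estimated correlation). In R47H/CV with tau disease-associated genes were split, 12 up and 21 down of 37 (FDR = 0.00115, and 0.221 with an estimated correlation). In R47H/CV under vehicle LXR targets fell, 14 of 23 with 3 higher (FDR = 0.00137, and 0.0789 with an estimated correlation). Tau in APOE3 R47H/CV lowered 26 of 27 cholesterol synthesis genes with 0 higher (median -1.27, FDR = 1.79e-07, and 0.166 with an estimated correlation), and in APOE4 CV/CV 24 of 27 with 0 higher (median -1.65, FDR = 1.74e-08, and 0.2 with an estimated correlation). Proliferation genes fell with tau in APOE3 R47H/CV, 36 of 45 with 3 higher (FDR = 0.000177, and 0.414 with an estimated correlation), and did not pass in APOE4 R47H/CV (6 up, 28 down, FDR = 0.106).

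The DNA sensor and its signalling partner moved apart with tau. After scaling Mb21d1 rose in each genotype, to 39.7 ± 1.15 CPM in APOE3 CV/CV, 38.1 ± 2.11 in APOE3 R47H/CV, 39.0 ± 1.61 in APOE4 CV/CV and 36.4 ± 3.21 in APOE4 R47H/CV, whereas Tmem173 fell in 3 of them and did not pass in APOE3 R47H/CV. Rises as small as those of Mb21d1 depend on the scaling, whose factors averaged 1.158 in APOE3 CV/CV with vehicle and 0.797 with tau. The tau response of Tmem173 was more negative in R47H/CV than in CV/CV in APOE4 (-0.63, FDR = 5.95e-05), and that of Mb21d1 did not differ (-0.29, FDR = 0.132). A candidate hypothesis is that interferon induced by tau acts back on Mb21d1, itself an interferon-stimulated gene, which may be tested by blocking the interferon receptor before the fibrils are added. Before scaling, Cdkn1a held 7651 of 20056483 counts in replicate 1 of APOE3 CV/CV with vehicle. With tau it held 5854 of 19143820 counts in replicate 1, a lower share. The rise of Cdkn1a after scaling with a fall of Cdkn2a in CV/CV leaves open whether cells stop dividing for long, and staining for both proteins with a label of DNA synthesis would separate the cases. Cell counts, culture purity and the origin of each replicate are not given in the sources used here. APOE3 R47H/CV and APOE4 R47H/CV have no sex in common by their sex-linked genes, so a comparison within a sex needs new cultures.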
